A study of Caenorhabditis elegans with 10 samples.

How the data were processed

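RNA abundance was measured in Caenorhabditis elegans dauers, the arrested larval stage, of 2 genotypes, the daf-2 mutant e1370 and a double mutant that also carries the chd-7 allele gk290, with 5 libraries of each. They are called daf-2 and chd-7;daf-2. The daf-2 gene encodes the insulin-like receptor, and e1370 is a temperature-sensitive allele that gives dauers at 25°C. Per the labels' protocols, animals spent 10 days at that temperature from synchronized eggs, RNA was isolated with TRIzol, and libraries were made with an NEBNext Ultra II RNA kit. The labels do not say whether libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

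The authors deposited one table of whole-number counts per library, with a gene name and its read count, not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.5.4a, HTSeq 0.9.1 and DESeq2 1.20.0. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads from overlapping genes on opposite strands may therefore not be told apart. HTSeq's tallies name no gene and stayed out of library sizes and tests. Relative to the reads assigned to genes and tallies together, as computed per library, reads outside any gene were 3.50% ± 0.591 (SD, n = 5) in daf-2 and 3.81% ± 1.13 in chd-7;daf-2. Ambiguous reads were 2.19% ± 0.0758 and 2.21% ± 0.0961, and reads aligned to several places were 6.52% ± 0.651 and 8.27% ± 1.62. Because reads with several alignments are not counted, genes of near-identical families (histones, actins, some collagens and major sperm proteins) are uncertain.

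Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 20222 genes in the tables, 12499 passed filterByExpr with its defaults (minimum count 10, minimum total 15). Library sizes were scaled by TMM. Genotypes were compared with edgeR's quasi-likelihood F test (robust), using no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p given without another test's name is from this fit. The SE of a log2 fold change was its size divided by the square root of F. Normalised read counts are given as CPM, which use the TMM-scaled library sizes, and principal components used log2 CPM with a prior count of 2. The limit that a count of 0 allows (3 counts) lay between 0.200 and 0.409 CPM per library, and it covers counting error only.

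A total of 36 gene lists was fixed before the data were examined. The 34 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, against all other tested genes, and adjusted over lists. The test was repeated with an estimated correlation and on ranks. Members were counted at adjusted p over all genes and also adjusted over the list alone. The count expected of a list is its tested members at the share of all tested genes called in either direction (36.2%). The genes named in the text come from a rule set before the data were examined: chd-7 and daf-2; daf-7, dbl-1 and the called members of both TGF-beta lists; the 12 largest rises and 12 largest falls among called genes with mean CPM of at least 5 and no overlap between genotypes; and up to 4 called members of each other list with the lowest p, in both directions where both exist. Genes named outside this rule are marked where they appear. The text gives a part of the genes that the rule picks, and the others are not reported here.

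Gene positions and exonic lengths came from the Ensembl 115 annotation of WBcel235, matched by name for 12344 of the 12499 tested genes (98.8%). That annotation may differ from the one used for counting. Of 152 genes picked by the rule, 22 share at least 50 exonic bases with another annotated gene. Besides those marked where they appear, these include bli-3, clec-266, dhs-16, eat-4, elo-5, gei-3, grd-15, pqn-75, ptr-8 and sip-1. The genes ctb-1, ctc-2, ndfl-4, nduo-3, nlp-42 and sodh-1 had no matched position, so their overlap was not checked.

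The test was tried on counts simulated from these libraries' means and sizes for the 12499 genes. It recovered 22% of genes changed by 1.5-fold, 74% at 2-fold, 92% at 4-fold and 96% at 8-fold, and 3.87% of its calls were false. The simulation changed only 50 genes at each fold and a list of 30, and drew genes independently. These rates need not hold for the real comparison, where 36.2% of genes were called and libraries share structure. Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), 1 surrogate variable from sva 3.50.0, 3 other scalings, no filter and a stricter filter (at least 5 CPM in 5 libraries), a fold threshold of 1.5 (glmTreat), the replicate number as a factor, and leaving out each library. Fits without a set of 3 libraries and on either side of the second principal component were added after the data were seen. Exact permutation tests over all assignments of 5 and 5 libraries are two-sided, and the smallest p they can give is 0.00794. Figures were drawn with matplotlib 3.10.9.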

Results

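The data compared dauers lacking normal CHD-7, a chromatin-remodelling ATPase whose human counterpart CHD7 is mutated in CHARGE syndrome, with dauers carrying the daf-2 mutation alone. The series title names TGF-beta pathways as the subject. Total gene counts per library ranged from 7331885 to 14997608 reads, and between 15545 and 16907 genes had at least 1 read.

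The genotypes differed widely. Of 12499 tested genes, 4523 (36.2%) changed at an adjusted p under 0.05, with 2240 higher and 2283 lower in chd-7;daf-2. A change of at least 2-fold was seen for 967 higher and 870 lower genes. In 22.7% of tested genes the 5 libraries of one genotype did not overlap the 5 of the other, against 0.794% by chance. The first principal component separated the genotypes and held 59.8% of the variance, and the second held 13.8% and split the libraries within both genotypes. Pearson correlations of log2 CPM across genes were 0.955 to 0.988 within chd-7;daf-2, 0.957 to 0.990 within daf-2 and 0.881 to 0.941 between genotypes. No pair of libraries of a genotype agreed within sampling noise, by a chi-square of their counts per degree of freedom. Some pairs were much closer than others. The value was 3.83 for daf-2 replicates 4 and 5. It was 5.55 for chd-7;daf-2 replicates 1 and 2 and 6.58 for replicates 3 and 4, against 15.99 to 67.45 in all other pairs. Whether close pairs share a culture or batch was not tested, and if so there are fewer than 5 independent units per genotype. Without chd-7;daf-2 replicate 4 and daf-2 replicates 2 and 3, which differed from the others of their genotype in germline or yolk transcripts, 3603 genes changed.

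**Figure D1:**
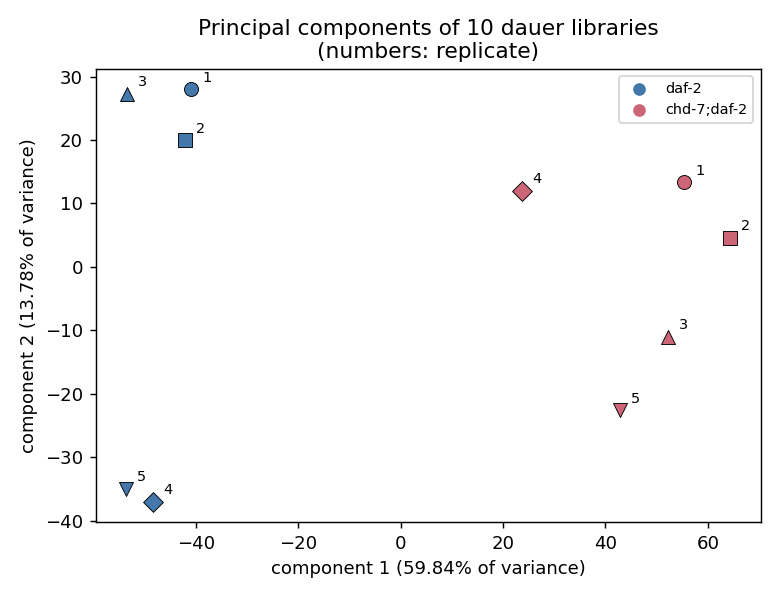
Principal components of log2 CPM over 12499 tested genes, with one point per library, colour for genotype and shape and number for replicate. The first component (59.8% of variance) parts the genotypes, and chd-7;daf-2 replicate 4 lies nearest to the daf-2 libraries.

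The chd-7 gene itself, at 4685865 to 4698575 on chromosome I in WBcel235 (minus strand), was read at 266 ± 20.8 CPM (SD, n = 5) in chd-7;daf-2 and 230 ± 22.4 CPM in daf-2. The log2 fold change was 0.21 ± 0.10 (SE) with an adjusted p of 0.138. The gk290 allele is a deletion, and a count over the whole gene does not show the deleted part, so this value does not check the labels. The daf-2 transcript was higher by 0.35 ± 0.11 on the log2 scale (adjusted p = 0.0330), a call that was lost without any 1 of chd-7;daf-2 replicates 1, 3, 4 and 5 and daf-2 replicates 1, 2 and 5.

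In the DAF-7 pathway, the TGF-beta branch that sensory neurons use to hold off dauer entry, 3 of 7 tested members rose and 1 fell. The count expected in both directions together was 2.53. The R-SMAD genes daf-8 and daf-14 rose by 1.11 ± 0.15 and 0.75 ± 0.08 on the log2 scale (adjusted p = 0.000269 and 7.39e-05), from 34.8 to 75.4 CPM and from 51.2 to 85.9 CPM. The gene daf-3, encoding the SMAD that acts against them, rose by 0.34 ± 0.08 (adjusted p = 0.00784). The shared type II receptor gene daf-4 fell by 0.60 on the log2 scale, from 275 ± 28.5 to 181 ± 12.7 CPM (adjusted p = 0.00130). The ligand gene daf-7, on chromosome III from 811844 to 813773, was at 3.61 ± 2.72 CPM in daf-2 and 9.11 ± 5.06 CPM in chd-7;daf-2, with overlapping libraries. Its log2 fold change of 1.32 ± 0.49 missed the threshold (adjusted p = 0.0554). It passed with DESeq2 (0.0190), limma-voom (0.0425) and total-count scaling (0.0499), each with 5 changed members, and without chd-7;daf-2 replicate 4 (0.0272) or daf-2 replicate 1 (0.00934). Adjusted over the list alone, 4 members were higher and 1 lower, and the list as a whole was not called by camera (adjusted p = 0.163). The daf-14 exons overlap a gene on the other strand.

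In the DBL-1 pathway, the BMP branch that sets body size, 8 of 21 tested members rose and 2 fell, with the same counts adjusted over the list alone. The count expected in both directions together was 7.6. The negative regulator gene lon-1 rose by 1.16 ± 0.17 on the log2 scale (6.14 to 13.8 CPM, adjusted p = 0.000477), and the transcription cofactor genes bro-1 and sma-9 rose by 1.34 ± 0.20 and 0.75 ± 0.18. The co-SMAD gene sma-4 rose by 0.72 ± 0.14 (adjusted p = 0.00224), and smaller rises were called for sma-10 (0.41 ± 0.13), drag-1 (0.46 ± 0.17) and sma-3 (0.28 ± 0.09). The metalloprotease gene adt-2 fell by 1.13 on the log2 scale, from 81.3 ± 6.01 to 37.3 ± 6.07 CPM (adjusted p = 6.03e-05). The ligand gene dbl-1, on chromosome V from 6758135 to 6760418, rose by 0.37 ± 0.12 (25.8 to 33.4 CPM, adjusted p = 0.0357). The list as a whole was not called (adjusted p = 0.251). The count of changed members was 6 without chd-7;daf-2 replicate 2, and the dbl-1 call was lost without any 1 of chd-7;daf-2 replicates 1 and 2 and daf-2 replicates 2, 3, 4 and 5 (adjusted p up to 0.0916). The calls of sma-3, sma-10 and drag-1 were each lost without at least 4 of the libraries in turn.

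**Figure D2:**
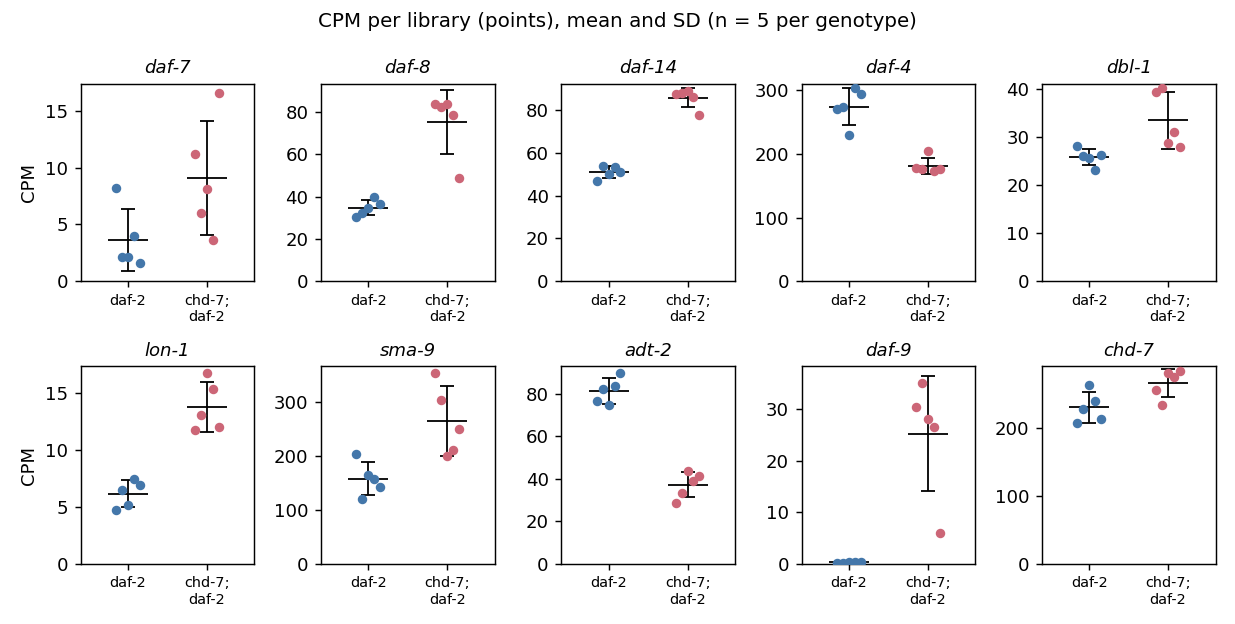
CPM of chd-7, daf-9 and members of both TGF-beta pathways, with a point per library, and the mean and SD (n = 5 per genotype) as a bar and whiskers, on axes that start at 0. The libraries separate by genotype for daf-14, daf-4, adt-2 and lon-1 and overlap for daf-7 and dbl-1.

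Cuticle collagen genes moved in both directions. Of 80 tested members, 21 rose and 10 fell (22 and 13 adjusted over the list alone), with a median log2 fold change of 0.02 and a mean of 0.14. The count expected in both directions together was 28.9, near the count seen. By library the list overlapped between genotypes, from -0.82 to 0.85 (log2, relative to the daf-2 mean) in daf-2 and from -0.39 to 0.60 in chd-7;daf-2. The largest rises were in dpy-9 (1.13 ± 0.787 to 38.2 ± 8.62 CPM, log2 fold change 5.06 ± 0.36) and col-42 (44.9 ± 11.1 to 858 ± 188 CPM, 4.26 ± 0.23). A further rise was in col-103 (58.7 to 534 CPM, 3.19 ± 0.15), and col-96 fell by 2.33 on the log2 scale (adjusted p = 0.000358). The list was called as higher (camera adjusted p = 0.0113), with adjusted p = 0.7095 with an estimated correlation and 0.410 on ranks. With the stricter filter 14 members changed.

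In collagen processing, 4 of 9 tested members rose and none fell (the same counts adjusted over the list alone), among them the dual oxidase gene bli-3 (1.15 ± 0.13) and the peroxidase gene mlt-7 (1.64 ± 0.20). The list's median was -0.05 and its mean 0.24, and it was not called (adjusted p = 0.0851). Of 22 cuticlin and other cuticle protein genes, 9 rose, including noah-1 (1.81 ± 0.17), and 2 fell, including cutl-14 (-1.57 ± 0.20), with the same counts adjusted over the list alone (adjusted p = 0.0550). Of 21 moulting genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.0518). Among them the transcription factor gene blmp-1 rose by 1.195 ± 0.17 and the lipoprotein receptor gene lrp-1 by 0.90 ± 0.14, whereas the protease gene nas-37 fell by 1.15 on the log2 scale. In the hedgehog-related and patched-related list, 15 of 56 rose and 8 fell (17 and 8 adjusted over the list alone), with ptr-8 (2.55 ± 0.12) and ptc-3 (1.65 ± 0.18) higher and grd-15 (-1.68 ± 0.31) lower. That list was called as higher (adjusted p = 0.0429), with adjusted p = 0.611 with an estimated correlation and 0.104 on ranks.

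Among called genes with a mean of at least 5 CPM and no overlap between genotypes, the largest rise was in daf-9, which encodes the cytochrome P450 that makes dafachronic acids, the steroid hormones that oppose dauer arrest. It lies on chromosome X from 6196927 to 6200823. Its level was 0.261 ± 0.126 CPM in daf-2 and 25.24 ± 11.2 CPM in chd-7;daf-2 (log2 fold change 6.56 ± 0.55, adjusted p = 1.74e-05). The daf-2 level stands on 14 reads over 5 libraries, near the counting limit, so the size of the fold change is uncertain. In chd-7;daf-2 replicate 5 daf-9 was at 6.02 CPM, while the other 4 libraries lay between 26.6 and 35.1. In the steroid hormone list, 5 of 10 tested members rose and none fell (5 and 1 adjusted over the list alone), among them strm-1 (2.14 ± 0.33), whose product consumes dafachronic acid precursors, and dhs-16 (1.39 ± 0.28). The list was not called (adjusted p = 0.0914).

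Further large rises within the same limits were in F14H8.2 (6.52 ± 0.47), F48C1.9 (6.28 ± 0.39), the zinc finger gene ztf-30 (5.23 ± 0.29), H39E23.3, grsp-1, H02F09.3, str-112, ref-1 (4.22 ± 0.27) and the astacin protease gene nas-9 (4.22 ± 0.47). In daf-2, F14H8.2, F48C1.9 and ztf-30 had only 10, 12 and 17 reads over 5 libraries, near the counting limit, so their fold sizes are uncertain. H02F09.3 shares exonic bases with a neighbour on the same strand. The largest falls within these limits were in F25B3.2 (67.2 ± 18.4 to 1.14 ± 0.436 CPM, log2 fold change -5.88 ± 0.28), the chemoreceptor gene str-18 (-5.24 ± 0.50) and the uterine lumen-expressed genes ule-1 (-5.11 ± 0.73) and ule-2 (-4.54 ± 0.76). The ule genes were highest in daf-2 replicates 2 and 3 (ule-1, 375 and 343 CPM against 67.0 to 96.7 in the other daf-2 libraries; ule-2, 79.8 and 71.2 against 11.9 to 18.98). T05F1.8, Y37H2C.1, T25B2.2 and C10C5.4 fell by 3.44 to 3.99 on the log2 scale. C10G8.4, C44B7.5, D1086.7 and F55B11.2 fell as well and varied more between daf-2 libraries (F55B11.2, 96.1 ± 65.1 CPM). Like the ule genes, each of them was highest in daf-2 replicates 2 and 3 (F55B11.2, 151.5 and 180.5 CPM against 38.4 to 60.4 in the other daf-2 libraries). Within chd-7;daf-2 each was highest in replicate 4 (F55B11.2, 28 CPM). These falls therefore need not be independent of those of the ule genes.

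Germline transcripts were lower in chd-7;daf-2. Of 60 tested germline and oocyte genes, 45 fell and none rose (52 and 0 adjusted over the list alone), with a median log2 fold change of -1.99. The Piwi gene prg-1 fell by 1.51 on the log2 scale (48.4 ± 10.6 to 17.1 ± 7.28 CPM, adjusted p = 0.000935), and the Nanos gene nos-1 fell by 2.49. The list was called as lower (camera adjusted p = 7.13e-12), with adjusted p = 0.611 with an estimated correlation. The fall was uneven between libraries. Relative to the daf-2 mean, the list lay at -2.23, -3.42, -2.98 and -2.96 (log2) in chd-7;daf-2 replicates 1, 2, 3 and 5 but at -0.41 in replicate 4, inside the daf-2 range of -0.44 to 0.74.

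Cell cycle, replication and histone genes were lower as well. Of 40 cell cycle genes, 22 fell and 2 rose (24 and 2 adjusted over the list alone, camera adjusted p = 9.95e-05), with adjusted p = 0.628 with an estimated correlation. The replicative helicase gene mcm-2 fell by 1.92 on the log2 scale, and the cyclin-dependent kinase gene cdk-4 rose by 0.79 ± 0.20. In chd-7;daf-2 replicate 4 the list lay at -0.12, against -1.31 to -0.89 in the other 4 libraries. Of 16 tested histone genes, 9 fell and none rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.000706), with adjusted p = 0.0536 with an estimated correlation. The yolk protein genes vit-2 (-3.36 ± 1.197) and vit-6 (-3.001 ± 0.94) fell with wide errors (adjusted p = 0.0486 and 0.0297, and both called adjusted over the list alone). Their reads were high in daf-2 replicates 2 and 3 (vit-2, 55.7 and 52.9 CPM) and low in the other 3 daf-2 libraries (1.57 to 3.41 CPM). Without daf-2 replicate 2 or 3 the vit-2 call was lost (adjusted p = 0.107 and 0.104), as was that of vit-6 (0.0682 and 0.0630), and both were also lost without any 1 of chd-7;daf-2 replicates 1, 2, 3 and 5. The sperm list had 1 tested member, nspd-7, outside the rule for named genes (2.21 against 4.86 CPM, adjusted p = 0.0555), called as higher adjusted over the list alone.

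**Figure D3:**
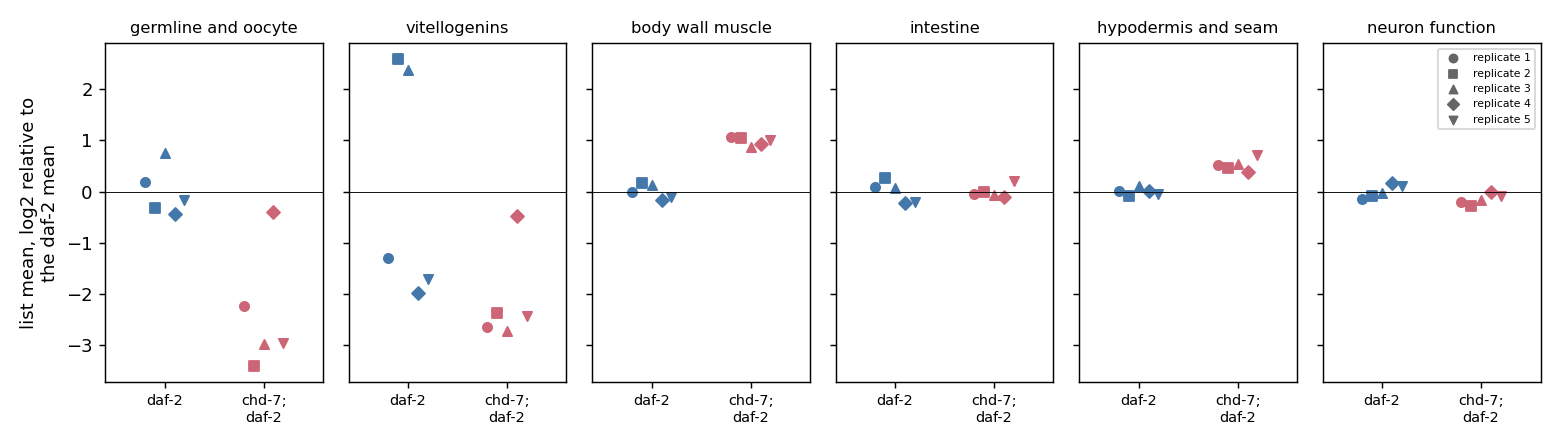
Mean log2 CPM of the tested members of 6 lists in each library, relative to the daf-2 mean, with colour for genotype and shape for replicate. Germline transcripts lie at -3.42 to -2.23 in 4 chd-7;daf-2 libraries and at -0.41 in replicate 4, whereas muscle transcripts are higher in all 5.

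Body wall muscle transcripts were higher in every chd-7;daf-2 library. Of 27 tested genes, 20 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.11. The alpha-actinin gene atn-1 rose from 12.4 ± 3.04 to 68.5 ± 4.75 CPM (2.47 ± 0.15, adjusted p = 1.96e-06), and the myosin light chain gene mlc-2 from 237 ± 38.7 to 681 ± 64.4 CPM (1.52 ± 0.13). The actin gene act-1 (1.45 ± 0.14), one of several near-identical actins, and the troponin I gene unc-27 (1.21 ± 0.13) rose too. The exons of act-1 and mlc-2 overlap genes on the other strand. This was the only list called with an estimated correlation (adjusted p = 0.00875, against 1.59e-12 with the preset value). Relative to intestine and neuron markers, the muscle list rose by 0.99 and 1.13 (log2; exact permutation p = 0.00794 for each, the smallest possible, adjusted to 0.0106 over 4 comparisons).

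Among other tissue markers, hypodermis and seam transcripts were higher, with 10 of 19 genes up and none down (12 and 0 adjusted over the list alone). The matrix receptor genes mua-3 and mup-4 rose by 1.08 ± 0.17 and 1.01 ± 0.17. The list was called (camera adjusted p = 0.00586), with adjusted p = 0.501 with an estimated correlation. Muscle exceeded it by 0.46 (exact permutation p = 0.00794, adjusted 0.0106). Intestinal markers went both ways, with 5 of 26 up and 8 down (the same adjusted over the list alone, adjusted p = 0.506). The exchanger gene nhx-2 and the peptide transporter gene pept-1 fell by 1.18 and 1.31 on the log2 scale, and the GATA factor gene elt-7 rose by 1.01 ± 0.21. Of 9 tested pharynx genes, 1 rose (gei-3, 1.36 ± 0.18) and 1 fell (pqn-75, -1.93 ± 0.23), the same adjusted over the list alone (adjusted p = 0.506). The muscle and pharynx lists differed by 0.45 between genotypes (exact permutation p = 0.294). Of 6 embryo markers, 1 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.251).

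Neuronal markers changed little as a group. Of 28 neuron function genes, 4 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.811), with the vesicular glutamate transporter gene eat-4 up by 0.70 ± 0.15. Of 24 chemosensory and cilia genes, 4 rose and 3 fell (3 and 1 adjusted over the list alone, adjusted p = 0.680). Among 74 neuropeptide genes, 18 rose and 13 fell (20 and 14 adjusted over the list alone, adjusted p = 0.659, median -0.10 and mean 0.14), with nlp-27 up by 2.38 ± 0.28 and nlp-42 down (-1.82 ± 0.20). In the axon guidance list, 11 of 35 genes rose and none fell (the same adjusted over the list alone), including the syndecan gene sdn-1 (0.89 ± 0.12) and the semaphorin gene smp-2 (0.59 ± 0.10). That list was called (adjusted p = 0.0429), with adjusted p = 0.611 with an estimated correlation.

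Insulin-like peptide genes were higher, with 6 of 20 up and 2 down (the same adjusted over the list alone, camera adjusted p = 0.0429, and adjusted p = 0.611 with an estimated correlation and 0.0735 on ranks). The peptide gene ins-27 rose by 2.58 ± 0.18 (7.08 to 42.3 CPM), ins-16 by 4.14 ± 0.57, and ins-22 fell by 1.98 on the log2 scale. In daf-2, ins-16 had only 13 reads over 5 libraries, near the counting limit. In the insulin signalling core, 3 of 14 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.811). Targets induced by the FOXO factor DAF-16 did not move together, with 3 of 20 up and 4 down (the same adjusted over the list alone, adjusted p = 0.997). The lysozyme gene lys-7 rose by 3.77 ± 0.40 and the alcohol dehydrogenase gene sodh-1 fell by 1.08 on the log2 scale (1885 to 889 CPM). Dauer-enriched genes had 3 of 22 up and 3 down (adjusted p = 0.744), and heat shock and unfolded protein response genes 4 of 20 up and 1 down (adjusted p = 0.744), both with the same counts adjusted over the list alone. The small heat shock gene hsp-16.2 rose by 1.01 ± 0.21.

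In metabolism, detoxification genes formed the largest called list. Of 149 cytochrome P450, UGT and GST genes, 54 rose and 17 fell (59 and 18 adjusted over the list alone, camera adjusted p = 0.000680), with adjusted p = 0.611 with an estimated correlation. Among them cyp-29A2 rose by 2.87 ± 0.28 and cyp-33C7 by 1.40 ± 0.10, and ugt-17 fell by 1.12 on the log2 scale. In fatty acid synthesis, 9 of 23 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.0942, and 0.0298 on ranks). The delta-12 desaturase gene fat-2 rose from 145 ± 39.8 to 640 ± 159 CPM (2.15 ± 0.23), the fatty acid synthase gene fasn-1 rose by 0.85 ± 0.13, and the elongase gene elo-5 fell by 2.24 on the log2 scale. Fatty acid breakdown had 9 of 42 up and 7 down (the same adjusted over the list alone, adjusted p = 0.659), with the carnitine palmitoyltransferase gene cpt-4 up by 1.98 ± 0.24. In the glyoxylate, gluconeogenesis and trehalose list, sodh-1 was the 1 of 18 members that fell and none rose (the same adjusted over the list alone, adjusted p = 0.414). Of 97 innate immune effectors, 24 rose and 21 fell (28 and 21 adjusted over the list alone, camera adjusted p = 0.0475, and adjusted p = 0.7095 with an estimated correlation and 0.0657 on ranks), with lys-1 up by 1.40 ± 0.15 and clec-266 down (-2.81 ± 0.38).

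Among housekeeping and regulatory groups, 2 of 77 ribosomal protein genes fell and none rose (0 adjusted over the list alone, adjusted p = 0.0942). Of 12 mitochondrially encoded genes, 6 rose and none fell (the same adjusted over the list alone, adjusted p = 0.0550, and 0.00815 on ranks), with ctb-1 up by 0.61 ± 0.17. Of 21 chromatin remodelling genes other than chd-7, 4 fell and none rose (2 and 0 adjusted over the list alone, adjusted p = 0.353), with ruvb-2 the lowest in p (-0.53 ± 0.12). In the heterochronic list, 4 of 15 rose and none fell (the same adjusted over the list alone, adjusted p = 0.200), with lin-46 up by 1.12 ± 0.17. Of the 34 tested lists, 11 were called, 8 higher and 3 lower. Changed members were near the expected count for cuticle collagens (28.9 expected), hedgehog-related (20.3), insulin-like peptide (7.24) and axon guidance genes (12.7). They exceeded it for detoxification (53.9), immune (35.1), muscle (9.77) and hypodermis genes (6.88). The 3 lists called as lower exceeded it too (germline 21.7, cell cycle 14.5, histones 5.79).

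**Figure D4:**
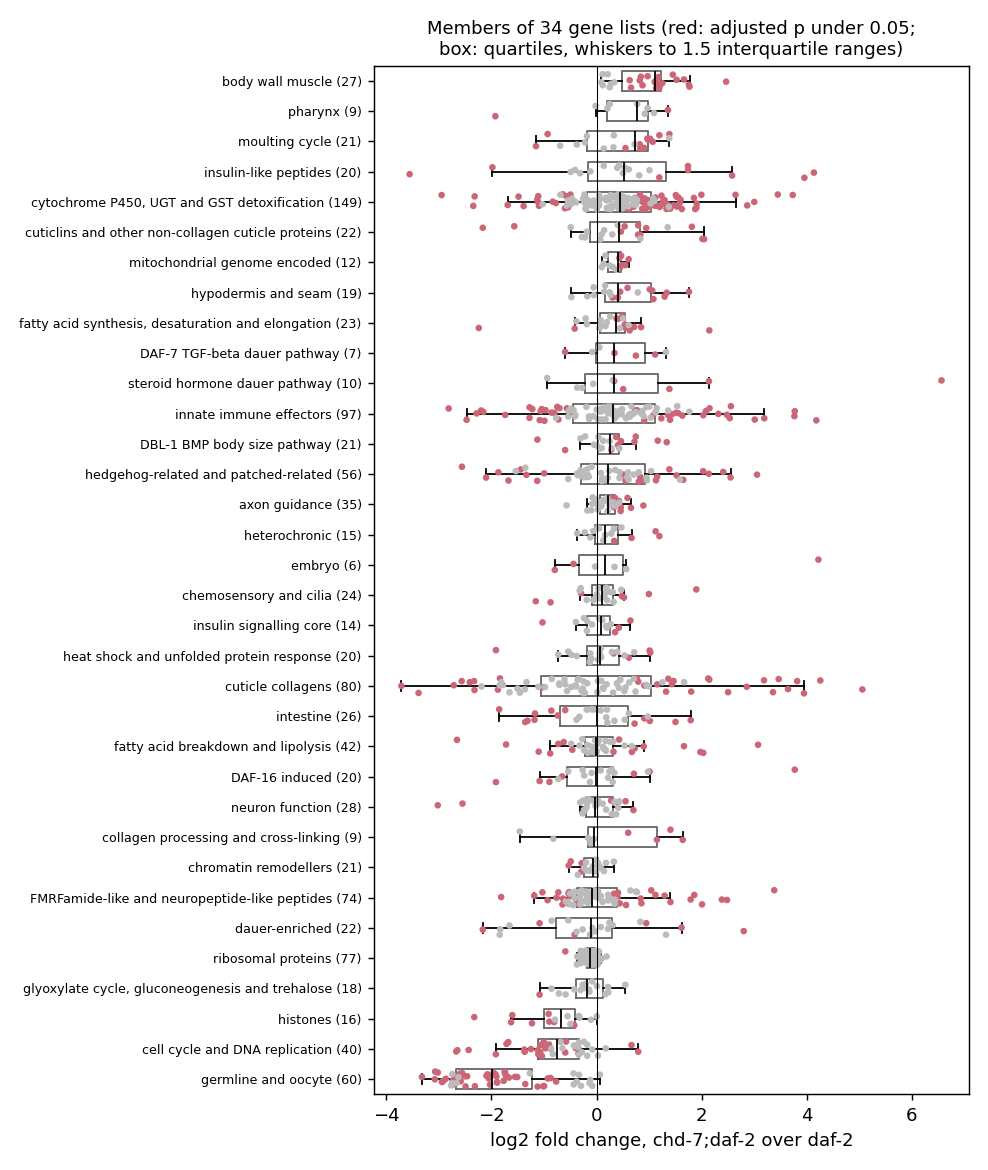
Log2 fold changes of chd-7;daf-2 over daf-2 for the tested members of 34 lists, ordered by median, with a point per gene, red at an adjusted p under 0.05, and boxes for quartiles. Body wall muscle has the highest median (1.11) and germline and oocyte the lowest (-1.99).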

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

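The tests of yolk-making adults, of muscle against other somatic lists, of the lowest daf-2 library, of the risen genes and lists, abundant genes and thinned mixtures for chd-7;daf-2 replicate 4, and of genes called on one side of the second component were chosen after the result was seen. The planned admixture test was first run with a minimum of 5 CPM, which had not been planned. After both values were seen, a demand that both clear the bound was made and later dropped, once the thinned mixtures had been compared. A library was singled out when its gap to the nearest of its genotype exceeded 0.71 of the range over 5 libraries (Dixon). This happened in 22 of 388 groups tested, and chance gives about 1 in 20, or 19.4.

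The first pattern is the fall of germline transcripts except in chd-7;daf-2 replicate 4. By the rule above that library was singled out in the vitellogenin list (-0.49 log2, against -2.74 to -2.38 in the others), vit-2 (8.72 CPM), msh-5 (7.30), icp-1 (16.23) and sip-1 (113). Yolk-making adults as the only source of germline and yolk transcripts in daf-2 would keep them in one ratio. Over the daf-2 libraries the yolk range exceeded the germline range by 3.39 log2 units. Adults added to a germline level of the dauers themselves would also widen the yolk range more, so the test cannot speak against such adults. Removing a trend with gene length left the germline median at -1.98. An admixture of daf-2 animals in replicate 4 is argued against by the planned test. Of 377 genes at least 4-fold lower without that library, 35.5% (95% exact binomial interval 30.7 to 40.6, with a bound of 30%) lay below 0.5 of the 60.4% share its germline genes showed. There were 2 unplanned forms, which did not clear their bounds. They gave 29.4% (23.9 to 35.3, bound 30%) of the 262 with at least 5 CPM in daf-2 and 13.4% (9.48 to 18.1, bound 10%) set against each gene's lowest daf-2 library. However, 20 mixtures of that share thinned from other libraries reached at most 24.4%, 23.4% and 3.02%, below all 3 intervals and for the 5 CPM form by a thin margin. The 24.4% passed the 10% predicted for an admixture. The intervals treat genes of 1 library as independent, though the germline list has an estimated correlation of 0.77. They may be too narrow, so the clearance of the planned bound (30.7 against 30) is not secure. Other tests did not decide by themselves: genes that rose at least 4-fold lay at a daf-2 share of 15.8% (bound 30.2%, SD 29.3 over the other 4 libraries), 0 of 8 lists called as higher lay above a mixture with a 34.9% share of daf-2 replicate 3 by more than 2 SD, 1 (body wall muscle, 0.905 against 0.529 log2) lay above one with a 60.4% share of the daf-2 mean, and 2 abundant genes, F25B3.2 (0.872 CPM) and str-18 (0.218 CPM), lay below 0.1 of the level needed, against a bound of 3. Some lists lay as a mixture predicts, within 2 SD of its level and more than 2 SD below the mean of the other 4 libraries. The hedgehog-related list did so in both mixtures (0.00537 against 0.232 and 0.216 log2). The insulin-like peptide list did so in that with the daf-2 mean (0.194 against 0.295). A smaller share, animals of another stage, genotype and developmental stage stay open, and beyond the ratio of yolk to germline transcripts none of these was tested.

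The second pattern is the rise of body wall muscle transcripts. A smaller germline share would raise all somatic transcripts alike, but the muscle list exceeded the intestine and neuron lists by at least 0.992 log2 units with an SE of 0.138 or less, and the hypodermis and seam list by 0.464 (SE 0.0948), whereas its difference of 0.455 to the pharynx list (SE 0.412, exact permutation p = 0.294) leaves that tissue undecided. Removing the trend with exonic length left a muscle median of 0.985, and the lowest median over 4 scalings was 1.08. An effect of the genotype, in muscle cells or in their share of the animal, may underlie it as a hypothesis from the same data, and neither was tested apart.

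The third pattern is the size of the response. Of 100 splits of the 10 libraries into 5 and 5, drawn from 126, 1 gave as many changed genes, the real one (4523), and the highest of the others gave 22. All other splits mix the genotypes, whose difference then counts as spread, so low counts in them are partly built in. The first rank of the real split argues against a chance split of exchangeable libraries. It does not address libraries that were raised or made together. The unlabelled split along the second principal component has sides that hold 3 and 3 and 2 and 2 libraries of the genotypes. A split so balanced cannot by itself make a difference between genotypes. Fits within its sides called 3167 and 3586 genes, but the balance had already settled this question, so these counts add nothing to it. Because of the balance, neither the 92.9% of genes called on one side with the same sign on the other nor the 99.7% among genes called on all 10 libraries decides anything.

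Reads aligned to several places, which the gene counts leave out, were more frequent in chd-7;daf-2 (8.27% against 6.52%, with no overlap between genotypes, exact permutation p = 0.00794, adjusted 0.0476 over 6 library measures). Within chd-7;daf-2, replicate 1 stood apart at 11.2%.

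Replicate 5 of chd-7;daf-2 was lowest in daf-9 (6.02 CPM), daf-8 (48.7), daf-14 (78.1), grsp-1 (21.7), nas-9 (67.3) and nlp-33 (22.5) and highest in dpy-11 (134). Other single libraries of chd-7;daf-2 were replicate 2 for daf-2 (174 CPM) and replicate 3 for daf-4 (204) and clec-266 (0.186). Replicate 1 of daf-2 was lowest in cpt-5 (0.0854 CPM), mua-3 (15.6), lin-46 (7.25) and the moulting list (-0.39 log2). Replicate 2 of daf-2 was highest in nduo-3 (67.6 CPM) and the mitochondrially encoded list (0.45 log2).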

How the results depend on the processing

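Fits without 3 libraries and on either side of the second component were chosen after the data were seen. The count of changed genes (4523) lay between 3167 and 5569 in all fits but that with a 1.5-fold threshold, where 1214 changed (761 higher, 453 lower). In every fit the genes shared with the main calls had the same direction. All fits use these libraries or a part of them, so this agreement was nearly built in. DESeq2 called 5247 and limma-voom 4949. Other scalings gave 4198 to 4593 and moved the median of all genes to -0.06 at most. The 1.5-fold threshold left 1 DAF-7 member, 3 DBL-1 members and 18 collagens, since it asks for more than a change from 0. The stricter filter, which tests fewer genes, left 14 collagens. On the positive side of the second component, with 6 libraries, 1357 genes were lower and 20 collagens changed. On the negative side, with 4, 6 DBL-1 members changed. With an estimated correlation 1 list was called. The first component held 75.1% of the variance over the 500 most variable genes. The cause of these shifts was not tested beyond the fewer genes or libraries.

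Leaving out each library gave 3358 to 4617 changed genes, 6 to 10 DBL-1 members (6 without chd-7;daf-2 replicate 2) and 7 to 15 called lists (7 without daf-2 replicate 1). The daf-2 transcript's call was lost without chd-7;daf-2 replicates 1, 3, 4 or 5 or daf-2 replicates 1, 2 or 5. Libraries share replicate numbers, and deviations of same-numbered libraries correlated at 0.30, 0.33, -0.19, -0.18 and 0.24. Pairs of unlike number reached 0.34 (chd-7;daf-2 replicate 5 with daf-2 replicate 4) and 0.31 (chd-7;daf-2 replicate 4 with daf-2 replicate 3). The numbers therefore do not pair all libraries, and a pairing of some of them stays open. With the replicate block 4764 genes changed, 4168 of them shared with the main comparison, and 15 lists were called, the 11 of that comparison and moulting, steroid hormone, mitochondrially encoded (adjusted p = 0.0474 each) and fatty acid synthesis (0.0476). At these depths and 5 libraries per genotype, 22% of simulated 1.5-fold changes were recovered, in a simulation where few genes changed and genes were drawn independently.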

Other observations

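The tests of gene families and chromosomes in this part were chosen after the data were seen, and the genes named fall outside the rule for named genes. Gene families sharing a symbol prefix, 67 with at least 15 tested members, gave further groups. Of 30 tested pals genes, some of which take part in the response to intracellular infection, 20 rose and 2 fell, with a median log2 fold change of 1.40 (camera adjusted p = 5.87e-07, and adjusted p = 0.508 with an estimated correlation). Examples were pals-5 (2.39 to 21.1 CPM, 3.13 ± 0.30) and pals-14 (13.3 to 163 CPM, 3.60 ± 0.63). Of 92 fbxa F-box genes, 36 rose and 6 fell (adjusted p = 0.00100), and of 184 nuclear hormone receptor genes, 47 rose and 8 fell (adjusted p = 0.01003), both with adjusted p = 0.778 with an estimated correlation.

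Nuclear pore genes were lower, with 15 of 24 npp genes down and none up (adjusted p = 0.000623, and adjusted p = 0.778 with an estimated correlation), including npp-9 (362 to 152 CPM, -1.25 ± 0.20). Germline and cell cycle genes fell too (45 of 60 and 22 of 40). Relative to the daf-2 mean, npp genes lay at -0.22 (log2) in chd-7;daf-2 replicate 4, the highest library of its genotype in both of those lists, and at -0.56 to -0.30 in the other 4 libraries. Chemoreceptor genes of the srx family had 8 of 27 down and 3 up (adjusted p = 0.0360, and adjusted p = 0.778 with an estimated correlation).

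Changed genes were slightly more frequent on chromosome V (39.5% of 2650, Fisher's exact p = 8.75e-05) and less frequent on X (32.2% of 1801, Fisher's exact p = 9.60e-05) than elsewhere, before adjustment over 6 chromosomes. On V only the share of higher genes stood out (21.13%, against 16.25 to 18.2% on all others). On X only the share of lower genes did (14.55%, against 17.88 to 20.44% on all others). Fisher's test treats genes as independent, which neighbouring genes need not be. A linked strain background could raise the share of changed genes near the chd-7 allele, a prediction written before its result was seen. Within 2 Mb of chd-7 36.5% of 605 genes changed, against 36.2% of the other genes (Fisher's exact p = 0.862), so an excess was not detectable, and a small one cannot be told apart from none.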
